A study of Homo sapiens with 6 samples.

How the data were processed

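Messenger RNA of the neuroblastoma line SK-N-AS was measured in 3 cultures, Monolayer, Sphere and iCSC, on 2 Affymetrix HG-U133 Plus 2.0 arrays each, 6 arrays in all. Per the labels' protocols, total RNA was isolated on RNeasy columns, and 200 ng of it were amplified and labelled with biotin by the MessageAmp Premier method. The deposited value table holds 1 log2 signal per probe set and array, made by the authors with GCRMA, and Partek is the other program named in the submitters' processing notes. GCRMA corrects each probe for the background that its base composition predicts, brings the arrays to a common distribution and summarises the probes of a probe set. The versions, the settings and what Partek was used for are not given in the sources used here. GCRMA pulls unexpressed probe sets to a narrow band of low values, so log2 fold changes that start from this band overstate what was measured. The array medians over all 54675 probe sets lay between 2.78 and 2.83, and 34.3% to 35.2% of the probe sets reached log2 5 on an array.

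Groups were taken from the sample titles and the culture and pretreatment labels. Probe sets were named through the platform's annotation, with symbols updated by Entrez identifier against a RefSeq gene table of the human assembly GRCh38.p14, which served for names and for the chromosome and order of genes. Of the probe sets, 62 were controls, 41091 carried a single gene symbol, 1801 carried several and 11721 carried none. The update matched 41037 probe sets. Probe sets with several symbols or none stayed out of the gene tests and were fitted apart. A probe set entered when its log2 value was at least 5 on at least 2 of the 6 arrays, which 18059 single-symbol probe sets did. Per gene, the probe set with the highest mean over all arrays was used, which left 10459 genes. Among 4742 genes with several passing probe sets, 149 in Sphere against Monolayer, 18 in iCSC against Sphere and 187 in iCSC against Monolayer had probe sets called in opposite directions.

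Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean per culture over all 6 arrays and no covariate, and variances were moderated by empirical Bayes with a mean-variance trend on 3 residual degrees of freedom. Each of the 3 contrasts was tested on both sides, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE). Where all arrays of a culture lay under log2 5, the limit taken as background, the fold is a lower bound computed with each value under the limit set to 5, and is written as "at least". The p-value beside such a fold comes from the values as deposited and tests their change, not the bound. Where only some arrays lay under it, their number is given. Gene lists fixed in advance, 38 in number and 34 with enough tested members, were tested with limma's camera at a preset correlation between genes of 0.01, for lists with at least 5 tested members, adjusted over the lists of a comparison. The same lists were tested with a correlation estimated from the residuals and with fry, and their members were counted over all genes and adjusted over the list alone. List medians are also given with every value under 5 set to 5, while the p-values beside them come from the values as deposited unless an alternative is named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

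The model was tested on simulated arrays with the real means and residual spreads, 10459 genes and 200 changed genes, 50 per fold size. For Sphere against Monolayer it recovered 42% of changes of 1.5-fold, 82% of 2-fold, 100% of 4-fold and 98% of 8-fold, with 10 false among 171 calls. For iCSC against Sphere the shares were 34%, 78%, 94% and 100%, with 11 false among 164 calls. For iCSC against Monolayer they were 22%, 82%, 98% and 100%, with 8 false among 159 calls. Far fewer genes changed in these simulations than were called in the data (38.5% to 59.0%), and the adjustment is stricter when few genes change. The shares therefore do not give the power of the real comparisons.

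The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 called genes with the largest positive and the 8 with the largest negative fold change whose arrays did not overlap between the cultures, up to 4 called members of each list, and 13 stem cell and reference genes whatever their values. The text names part of the genes the rule gives. DDC and MAGEA6 were added as large changes measured above background in both cultures, chosen after their values were seen, and so were TEX14, PRAME and the values of some genes in a further comparison. POU5F1 is 1 of the 13, but its probe set carries several symbols and it was not analysed here. Alternatives were no filter and a stricter filter at log2 7, a floor at log2 5, renewed quantile normalization, median centring, the mean of a gene's probe sets, leaving out probe sets with the suffixes x_at and s_at, other variance models, fits of the compared cultures alone, the replicate number as a block, stricter thresholds and leaving out each array in turn. An array left alone in its culture was assumed to vary like the other cultures. Removal of each chromosome's median deviation was added after the data were seen. The overlap of the comparisons that share the Monolayer arrays was set beside 100 simulated data sets with no change. Groups of 2 arrays are too small for a count of other splits of the arrays. No detection flags were used.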

Results

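SK-N-AS, a human neuroblastoma cell line, was profiled on 6 expression arrays in 3 cultures of 2 arrays each. Monolayer cells grew as an attached layer, and Sphere cells grew as spheroids without serum. iCSC cells, named for induced cancer stem cells, were first exposed as a monolayer to 2.5 uM 5AdC (5-aza-2'-deoxycytidine, an inhibitor of DNA methyltransferases) for 5 days and were then moved to serum-free spheroid culture. The series asks how the stem cell phenotype differs between these cultures. Levels are log2 GCRMA signals, given as mean ± SD over the 2 arrays of a culture (n = 2 throughout), and 10459 genes were tested with limma and Benjamini-Hochberg adjustment. Nothing in the labels says that the 2 arrays of a culture came from separate cell cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

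Arrays of one culture resembled each other far more than arrays of different cultures. Over the tested genes, which are not independent replicates, Pearson's r was 0.996 between the Monolayer arrays, 0.992 between the Sphere arrays and 0.984 between the iCSC arrays. Between cultures it ranged from 0.729 to 0.749 for Monolayer and Sphere, from 0.791 to 0.805 for Monolayer and iCSC, and from 0.838 to 0.859 for Sphere and iCSC. The first principal component, with 65.9% of the variance, separated Monolayer from both spheroid cultures, and the next, with 30.9%, separated iCSC from Sphere. The difference between the 3' and 5' control probe sets of ACTB, a sign of RNA integrity, was 1.47 and 1.40 on the iCSC arrays, 1.25 and 1.16 on the Monolayer arrays, and 1.22 and 1.21 on the Sphere arrays, while that of GAPDH lay between 0.12 and 0.20 on all 6.

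Several stem cell factors were measured in iCSC and not in the other cultures. Only 8 of the 22 pluripotency and stem cell factors on the list entered the test. LIN28A, SALL4, DPPA4, ZFP42 and KIT were among those under log2 5 on all 6 arrays. SOX2, PROM1 and MYCN, under it on all Monolayer and Sphere arrays, entered the test through iCSC, so the filter set their direction. SOX2, a transcription factor of neural and embryonic stem cells, reached 8.86 ± 0.55 in iCSC against 1.98 ± 0.01 in Sphere and 2.03 ± 0.02 in Monolayer, at least 14.5-fold higher than either (limma, adjusted p = 9.22e-06 and 5.61e-06). In iCSC 2 of its 4 probe sets stood above the limit of log2 5. PROM1, the surface protein CD133 used to enrich stem-like tumour cells, reached 10.56 ± 0.17 against 2.60 in both other cultures, at least 47.2-fold higher (adjusted p = 2.03e-06 against Sphere and 7.41e-07 against Monolayer). LIN28B, an RNA-binding protein that blocks let-7 microRNA processing, rose in steps from 2.08 ± 0.02 in Monolayer to 6.41 ± 0.37 in Sphere and 7.88 ± 0.01 in iCSC. Sphere was at least 2.66-fold above Monolayer (adjusted p = 1.08e-05), and iCSC was 1.47 ± 0.22 (log2, SE) above Sphere (adjusted p = 0.00265) and at least 7.39-fold above Monolayer (adjusted p = 4.62e-06). MYCN, the oncogene amplified in many high-risk neuroblastomas, lay at 2.70 in Monolayer and 2.71 in Sphere and at 7.97 and 5.62 on the iCSC arrays, at least 3.48-fold higher (adjusted p = 0.00429 against Sphere and 0.00259 against Monolayer), in 1 of its 10 probe sets. The MYCN calls were lost with values under 5 set to 5 (adjusted p = 0.0880 and 0.0685) and without variance moderation (0.0778 and 0.0561). Over 17 alternatives the adjusted p ranged from 1.93e-05 to 0.0880 against Sphere and from 1.38e-05 to 0.0685 against Monolayer.

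**Figure D1:**
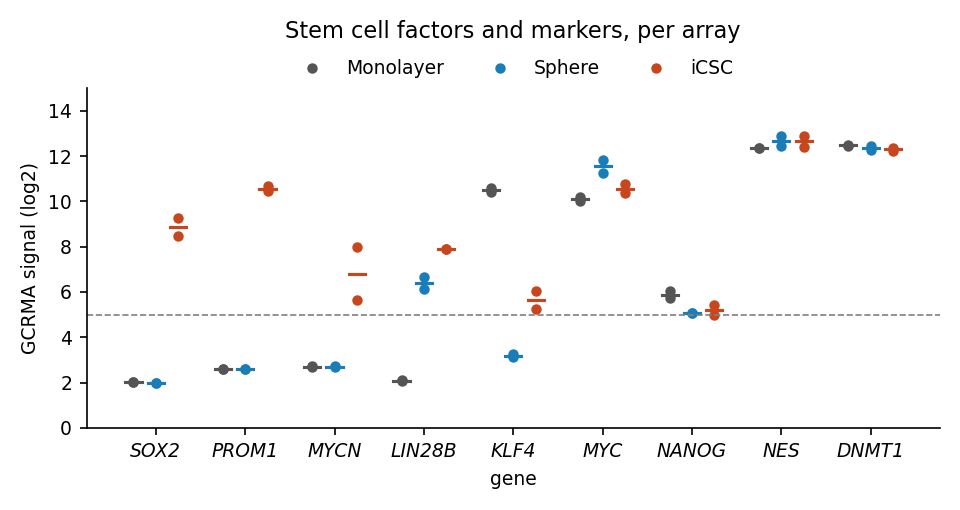
GCRMA signal (log2, y axis) of 9 stem cell factors and markers (x axis) on each of the 6 arrays, coloured by culture, with a short line at each culture's mean and a dashed line at the limit of log2 5. SOX2, PROM1 and MYCN lay above the limit on both iCSC arrays and under it on the Monolayer and Sphere arrays, and KLF4 was highest in Monolayer.

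Other factors of this set moved otherwise. KLF4, a transcription factor of pluripotent and epithelial cells, fell from 10.51 ± 0.14 in Monolayer to 3.19 ± 0.07 in Sphere, at least 45.6-fold (limma, adjusted p = 3.64e-06), and stood at 5.65 ± 0.58 in iCSC, a log2 change of -4.86 ± 0.28 from Monolayer (adjusted p = 2.77e-05). In 1 of its 2 probe sets KLF4 was at least 1.57-fold higher in iCSC than in Sphere (adjusted p = 0.000890, range over 18 alternatives 0.000375 to 0.111), a call lost with values under 5 set to 5 (0.111). MYC, a driver of growth and proliferation, was 1.44 ± 0.22 higher in Sphere than in Monolayer (log2, adjusted p = 0.00161). It changed by -0.99 ± 0.22 from Sphere to iCSC (adjusted p = 0.0133, range 0.00843 to 0.116), a call lost without Sphere replicate 1 (0.0661), without iCSC replicate 2 (0.0574) and without variance moderation (0.116). MYC differed by 0.45 ± 0.22 between iCSC and Monolayer, which did not pass the test (adjusted p = 0.128). NANOG, a pluripotency factor, was near the limit at 5.88 ± 0.20, 5.06 ± 0.02 and 5.23 ± 0.31 in Monolayer, Sphere and iCSC.

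The NANOG change from Monolayer to Sphere was -0.82 ± 0.22 (limma, adjusted p = 0.0164, range 0.00272 to 0.0864), lost without Monolayer replicate 2 (0.0864), Sphere replicate 1 (0.0619), Sphere replicate 2 (0.0621) and variance moderation (0.0635). From Monolayer to iCSC it was -0.66 ± 0.22 (adjusted p = 0.0392, range 0.00494 to 0.168), lost under 9 of 18 alternatives, among them without Monolayer replicate 1 (0.0637), Monolayer replicate 2 (0.168), Sphere replicate 1 (0.0606), Sphere replicate 2 (0.0605), iCSC replicate 2 (0.120) and with the replicate block (0.0540). NES, an intermediate filament of neural progenitors, lay at 12.35, 12.67 and 12.65 in Monolayer, Sphere and iCSC, and DNMT1, the maintenance DNA methyltransferase, at 12.48, 12.34 and 12.30. Neither passed the test in any comparison, except NES in iCSC against Monolayer without iCSC replicate 1 (adjusted p = 0.0481, range 0.0481 to 0.832). Of the reference genes, TBP lay between 8.85 and 8.94 and GAPDH at 14.93 in Sphere and 14.90 in iCSC, without a call. Only with chromosome medians removed was GAPDH called lower in Sphere and iCSC than in Monolayer (limma, adjusted p = 0.000676, range 0.000676 to 0.891, and 0.000493, range 0.000493 to 0.899). ACTB fell slightly from 15.52 ± 0.02 in Monolayer to 15.27 ± 0.10 in Sphere (adjusted p = 0.0306, range 0.0133 to 0.163) and 15.15 ± 0.11 in iCSC (0.00742, range 0.00273 to 0.0645). The Sphere call was lost under 7 alternatives, among them without Monolayer replicate 1 (0.156), Monolayer replicate 2 (0.120) or Sphere replicate 1 (0.163). ACTB in iCSC lost its call without Monolayer replicate 1 (0.0645), Monolayer replicate 2 (0.0519) or variance moderation (0.0562).

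Sphere against Monolayer asks what spheroid culture without serum changed. Transcripts of sympathetic neuroblasts and neurons were higher in Sphere. Whether the same cells changed or other cells came to make up the culture was not tested. DLK1, a membrane protein of the Notch ligand family, rose from 2.81 ± 0.24 to 13.92 ± 0.07, at least 485-fold (limma, adjusted p = 6.05e-07), and STMN2, a microtubule regulator of growing axons, rose at least 294-fold to 13.20 ± 0.23. The neuropeptides VIP and GAL rose at least 161-fold and at least 130-fold (adjusted p = 0.000164 and 0.000177). In the other direction, the receptor tyrosine kinase AXL fell from 13.38 ± 0.01 to 2.92 ± 0.37, at least 334-fold (adjusted p = 1.10e-06), and the adhesion and guidance genes PCDH10 and EPHA3 fell at least 279-fold and 236-fold. In all, 6176 of 10459 genes (59.0%) were called, 3134 higher and 3042 lower in Sphere, against 6616 at an unadjusted p under 0.05. At least 2-fold changes made up 1683 of the higher and 1311 of the lower calls.

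Of 19 measured sympathoadrenal (adrenergic) neuroblast genes, 17 rose, none fell and 2 did not pass, 17 adjusted over the list alone. A mean under log2 5 in Monolayer and above it in Sphere was found for 9 of them, so the filter favoured a rise of these. The list stayed called with no filter. CHGA, the chromogranin of dense-core vesicles, rose by 9.03 ± 0.09 (log2, SE) to 13.98 ± 0.07, with 1 of the 2 Monolayer arrays under the limit, and DDC, which makes dopamine from L-DOPA, rose by 6.15 ± 0.42 to 12.97 ± 0.17. ELAVL4, a neuronal RNA-binding protein, rose at least 156-fold. The list median was 3.86, or 2.75 with values under 5 at the limit (camera, adjusted p = 3.65e-08, but adjusted p = 0.673 with an estimated correlation). Of 23 neuronal differentiation genes, 20 rose and none fell, 20 also adjusted over the list alone. They included the growth cone protein GAP43 (at least 36.6-fold) and the neurofilament NEFM (at least 42.3-fold), and the median was 3.14, or 2.32 at the limit (camera, adjusted p = 6.45e-07, and adjusted p = 0.673 with an estimated correlation). GAP43 and NEFM, under the limit in Monolayer, entered the test through the other cultures, and this list too stayed called with no filter.

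Most genes of the mesenchymal neuroblastoma state and most SRF, YAP and cytoskeletal targets fell. Of 23 mesenchymal genes, 16 fell and 4 rose, 20 adjusted over the list alone. The median was -2.06, which was the same at the limit (camera, adjusted p = 0.00926, and adjusted p = 0.673 with an estimated correlation). The transcription factors RUNX2 and FOSL1 fell at least 21.7-fold and 24.7-fold, and the receptors NOTCH2 and TGFBR2 fell at least 38.4-fold and 26.9-fold (largest adjusted p = 0.000346, limma). Of 20 targets of SRF and YAP and cytoskeletal genes, 15 fell and 2 rose, 18 adjusted over the list alone. Their median was -2.95 (camera, adjusted p = 8.03e-06, and adjusted p = 0.673 with an estimated correlation). The secreted matrix protein CCN2 fell at least 45.3-fold and the Hippo pathway proteins AJUBA and AMOTL2 at least 132-fold and 124-fold, and the matrix protein POSTN, outside this list, fell at least 108-fold. Integrins, cadherins and adhesion receptors did not fall as a list: 12 of 23 rose and 7 fell, with a median of 0.62 (camera, adjusted p = 0.314). All 8 measured Hedgehog pathway genes fell, also adjusted over the list alone. The median was -3.25, or -2.31 at the limit (camera, adjusted p = 0.000394, and adjusted p = 0.673 with an estimated correlation). Among them the ligand co-receptors GAS1 and BOC changed by -4.01 ± 0.10 and -4.21 ± 0.20 (log2, SE), and the transcription factor GLI2 fell from 8.33 ± 0.07 to under the limit (4.03 ± 0.78). With no filter 12 Hedgehog genes entered, and their median was -1.74.

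In the TGF-beta and BMP list, 14 of 22 genes fell and 5 rose in Sphere, 20 adjusted over the list alone. Their median was -1.32, or -0.82 at the limit (camera, adjusted p = 0.0301, and adjusted p = 0.673 with an estimated correlation). The secreted antagonists NOG and FST fell at least 38.5-fold and 21.5-fold, while the receptor BMPR1B rose at least 33.9-fold (largest adjusted p = 3.42e-05, limma). The list's call was lost without probe sets of the suffixes x_at and s_at (adjusted p = 0.221, range over 16 alternatives 0.0138 to 0.221), where the median was -0.86, and with no filter the median was -0.67. Of 21 endoplasmic reticulum chaperone and unfolded protein response genes, 17 fell and 1 rose, 18 adjusted over the list alone. The median was -0.85 (camera, adjusted p = 0.000394, and adjusted p = 0.673 with an estimated correlation). SDF2L1 and MANF, proteins of the reticulum's lumen, changed by -2.03 ± 0.19 and -1.52 ± 0.19, and the member that rose was ERN1, a sensor of unfolded proteins, by 1.88 ± 0.15.

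Genes of the cell cycle were lower in Sphere. Of 36 G2/M and mitosis genes, 24 fell and none rose, 25 adjusted over the list alone. Their median was -0.62 (camera, adjusted p = 0.000259, and adjusted p = 0.931 with an estimated correlation). Without x_at and s_at probe sets the median was -0.39. The kinase AURKB, the kinesin KIF23 and the spindle protein NUSAP1 changed by -1.96 ± 0.15, -2.02 ± 0.11 and -1.20 ± 0.07 (log2, SE). Of 36 S phase and DNA replication genes, 18 fell and 5 rose, 23 adjusted over the list alone. The median was -0.31 (camera, adjusted p = 0.0342, and adjusted p = 0.931 with an estimated correlation). CCNE2, a cyclin of S phase entry, and the nucleotide synthesis enzymes TK1 and RRM2 changed by -2.27 ± 0.11, -1.72 ± 0.27 and -0.99 ± 0.13. The S phase call was lost without Monolayer replicate 1 (adjusted p = 0.0953), without Sphere replicate 1 (0.132), after renewed quantile normalization (0.0745) and without x_at and s_at probe sets (0.194). Over 16 alternatives its adjusted p ranged from 0.00802 to 0.194. The median fold change of a chromosome's genes was -0.46 for chromosomes 3 and 15 and 0.49 for chromosome 12. PTPRC, the leukocyte phosphatase CD45, was measured at 11.74 ± 0.14 in Monolayer and 12.47 ± 0.07 in Sphere, whereas the leukocyte markers CD14, CD3D, CD3E, TYROBP and SPI1 stayed under the limit on all 6 arrays.

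**Figure D2:**
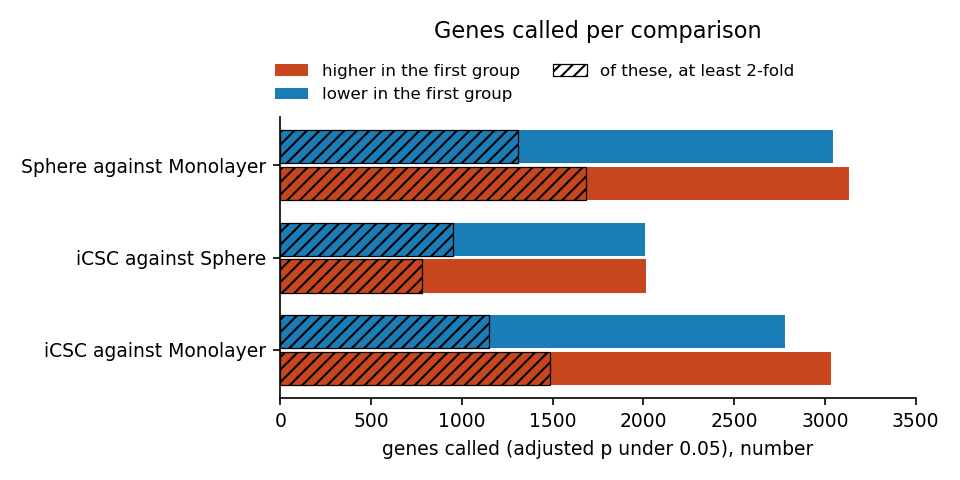
Number of genes called at an adjusted p under 0.05 (x axis) in each comparison, those higher in the first-named culture in red and those lower in blue, with hatching for changes of at least 2-fold. Calls were split nearly evenly between the directions in each comparison, with 3134 higher and 3042 lower in Sphere against Monolayer, 2014 and 2008 in iCSC against Sphere, and 3034 and 2778 in iCSC against Monolayer.

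iCSC against Sphere asks what the earlier 5AdC exposure changed among cells grown as spheroids. Of 41 cancer-testis and germline genes, a class mostly silent and methylated in adult tissues outside the testis, 10 were measured and all 10 rose, also adjusted over the list alone. Of these 10, 7 lay under the limit on both Sphere arrays and entered the test through their signal in iCSC, so their direction was set by the filter. SSX1 rose from 2.46 ± 0.01 to 11.77 ± 0.18, at least 109-fold, and MAGEA12 at least 137-fold (limma, adjusted p = 2.03e-06 for both). MAGEA1 rose at least 30.7-fold and GAGE1 at least 18.0-fold, and MAGEA6, measured in both cultures, rose by 6.18 ± 0.13 (log2, SE) to 13.28 ± 0.15. The list median was 6.06, or 3.68 with values under 5 at the limit (camera, adjusted p = 1.46e-09, and adjusted p = 0.213 with an estimated correlation). With no filter 32 list genes entered, of which 10 rose and none fell, and the median was 0.01 (camera, adjusted p = 4.40e-05, range over 16 alternatives 1.60e-10 to 0.00751). Single genes with large rises included the homeobox genes DLX1, PITX1 and DLX2 (at least 115-fold, 69.6-fold and 60.1-fold, largest adjusted p = 6.08e-06, limma), the annexin ANXA1 (at least 101-fold) and the collagen COL1A2 (at least 183-fold, to 12.51 ± 0.70). Fold changes in this comparison also differed by chromosome, with a median of -0.67 over the genes of chromosome 14, 0.47 over chromosome 15 and 0.45 over chromosome 9.

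PTPRC fell from 12.47 ± 0.07 to 2.86 ± 0.01 in iCSC, at least 177-fold (limma, adjusted p = 9.02e-07), and inflammatory signals fell beside it. CXCL10, a chemokine for T cells, fell at least 64.6-fold (adjusted p = 3.50e-06). Of 15 NF-kappaB and inflammatory genes, 11 fell and none rose, 12 adjusted over the list alone. Their median was -2.43, or -1.85 at the limit (camera, adjusted p = 6.46e-06, and adjusted p = 0.605 with an estimated correlation). The cytokines TNF and IL1B fell at least 20.2-fold and 8.23-fold, and the monocyte chemokine CCL2 changed by -4.04 ± 0.31 (log2, SE) from 15.52 ± 0.26. The list's median was -1.51 without Sphere replicate 2, -1.51 without x_at and s_at probe sets and -1.56 with no filter. In Sphere against Monolayer 9 of the 15 genes rose and 4 fell, with a median of 1.13 (camera, adjusted p = 0.169). In iCSC against Monolayer 2 rose and 5 fell, with a median of -0.36 (camera, adjusted p = 0.165).

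Neuroblast and neuronal genes were lower in iCSC than in Sphere. Of 19 sympathoadrenal genes, 14 fell, none rose and 5 did not pass, 14 adjusted over the list alone. The median was -1.67, or -1.05 at the limit (camera, adjusted p = 1.71e-06, and adjusted p = 0.605 with an estimated correlation). HAND1 and GATA3, transcription factors of the sympathoadrenal lineage, changed by at least 22.4-fold downward and by -4.12 ± 0.22 (log2, SE), and the granin CHGB by -5.27 ± 0.64, with a wide spread between the iCSC arrays (7.11 ± 1.40). With chromosome medians removed the median of this list was also -1.05, and it was still called (adjusted p = 9.04e-07). Of 23 neuronal differentiation genes, 20 fell and 2 rose, 22 adjusted over the list alone. Their median was -2.37, or -2.15 at the limit (camera, adjusted p = 1.71e-06, and adjusted p = 0.605 with an estimated correlation). STMN2 changed by -5.78 ± 0.23.

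Hedgehog genes and part of the Notch genes were higher in iCSC than in Sphere. All 8 measured Hedgehog genes rose, also adjusted over the list alone. The median was 2.13, or 1.59 at the limit (camera, adjusted p = 8.10e-05, and adjusted p = 0.342 with an estimated correlation). The transcription factor GLI2 rose at least 6.20-fold, its relative GLI3 by 3.03 ± 0.19 (log2, SE) and the co-receptor BOC by 2.89 ± 0.20. Of 15 Notch genes, 7 rose and 1 fell, 8 adjusted over the list alone. Their median was 0.64, or 0.46 at the limit (camera, adjusted p = 0.0194, and adjusted p = 0.605 with an estimated correlation). NOTCH2 rose at least 144-fold to 12.17 ± 0.38 and DLL3, a ligand that inhibits Notch in the same cell, by 3.22 ± 0.16. The member that fell was DTX3, a ubiquitin ligase, at least 13.9-fold. The Notch call was lost without iCSC replicate 1 (adjusted p = 0.0632) and without x_at and s_at probe sets (0.233), with a range of 0.00198 to 0.233 over 16 alternatives. The Notch median was 1.22 without Sphere replicate 2, 1.12 without iCSC replicate 2, 1.31 without x_at and s_at probe sets and 2.04 with the stricter filter. Against Monolayer neither list was called in iCSC. There 2 of 8 Hedgehog genes rose and 3 fell, with a median of -0.65 (camera, adjusted p = 0.275). Of the Notch genes 4 rose and 5 fell, with a median of -0.49 (camera, adjusted p = 0.854). The rises thus started from Sphere levels, where 8 Hedgehog and 11 of 15 Notch genes lay lower than in Monolayer. Of 36 G2/M and mitosis genes, 12 rose and 2 fell in iCSC against Sphere, 14 adjusted over the list alone. The median was 0.25 (camera, adjusted p = 0.0368, and adjusted p = 0.821 with an estimated correlation). AURKB rose by 1.43 ± 0.15, KIF23 by 1.17 ± 0.11 and NUSAP1 by 0.97 ± 0.07. This call was lost without Sphere replicate 1 (adjusted p = 0.265), without iCSC replicate 2 (0.248, median 0.09), with only these cultures in the fit (0.0507) and without x_at and s_at probe sets (0.214), and ranged from 0.000356 to 0.265.

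In all, 4022 of 10459 genes (38.5%) were called in iCSC against Sphere, 2014 higher and 2008 lower, against 5031 at an unadjusted p under 0.05. Of these, 781 higher and 949 lower genes changed at least 2-fold. The count was 2574 without Sphere replicate 1, 2281 without variance moderation and 2354 at an adjusted p under 0.01.

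**Figure D3:**
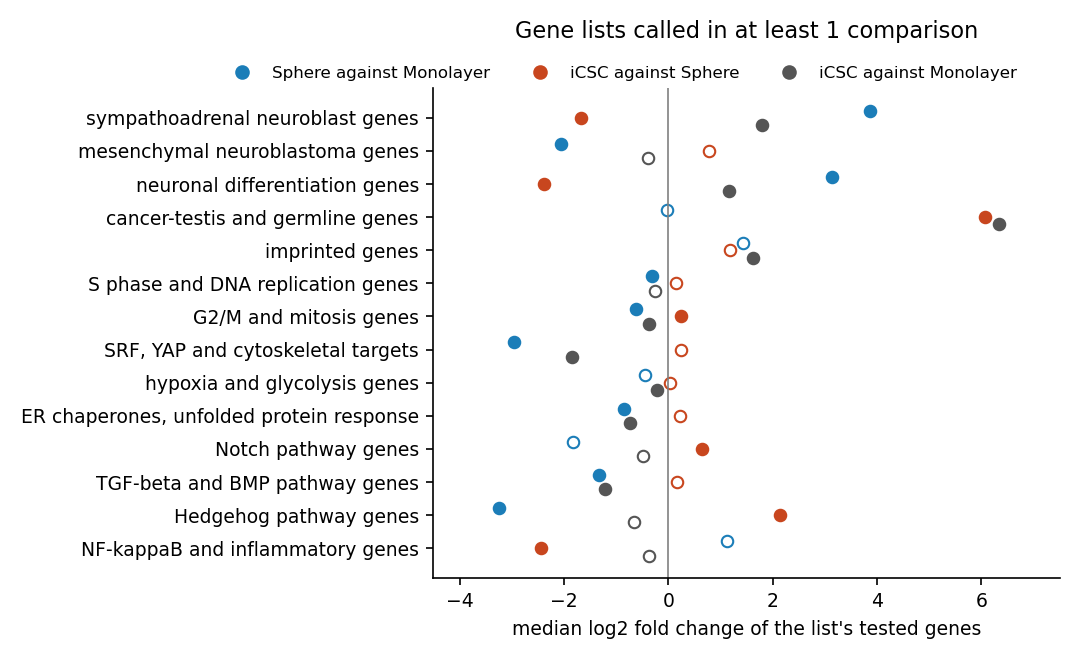
Median log2 fold change of the tested genes (x axis) of each gene list (y axis) called by camera in at least 1 comparison, coloured by comparison, with filled points where the list was called and open points where it was not. Sympathoadrenal and neuronal lists had medians of 3.86 and 3.14 in Sphere against Monolayer and of -1.67 and -2.37 in iCSC against Sphere, and the 10 measured cancer-testis genes had medians of 6.06 and 6.34 in the comparisons of iCSC with Sphere and with Monolayer.

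iCSC against Monolayer asks what the exposure and the spheroid culture changed together. The 10 measured cancer-testis genes were higher against Monolayer as well: all 10 rose, also adjusted over the list alone. Their median was 6.34, or 3.68 at the limit (camera, adjusted p = 5.37e-07, and adjusted p = 0.330 with an estimated correlation). Again 7 of the 10 lay under the limit on both Monolayer arrays and entered through iCSC, and with no filter 9 of 32 list genes rose and 1 fell, with a median of -0.01 although camera still called the list higher (adjusted p = 0.00570, range over 16 alternatives 1.60e-07 to 0.0379). SSX1 rose at least 109-fold and MAGEA12 at least 137-fold. DLK1 rose at least 149-fold to 12.22 ± 0.38, NELL2, a secreted neural glycoprotein, at least 114-fold, and the collagens COL6A3 and COL1A2 at least 75.7-fold and 183-fold (largest adjusted p = 9.40e-06, limma). PTX3, a secreted protein of inflammation, fell from 14.24 ± 0.07 to 2.76 ± 0.57, at least 605-fold (adjusted p = 1.12e-05), and PCDH10, EPHA3, the fatty acid receptor CD36 and PTPRC fell at least 279-fold, 236-fold, 114-fold and 107-fold. In all, 5812 genes (55.6%) were called, 3034 higher and 2778 lower, against 6422 at an unadjusted p under 0.05, and 1485 higher and 1147 lower genes changed at least 2-fold.

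Of 9 imprinted genes, 6 rose, none fell and 3 did not pass, 7 adjusted over the list alone. The median was 1.61, the same at the limit (camera, adjusted p = 0.00293, and adjusted p = 0.574 with an estimated correlation). Besides DLK1 they included MEG3, a maternally expressed RNA (at least 44.4-fold), the cell cycle inhibitor CDKN1C (from under the limit to 9.32 ± 0.49) and the receptor adaptor GRB10 (at least 5.74-fold). The median of imprinted genes was 0.10 with no filter, which admits 19 of them, and 3.30 with the stricter filter. Of 19 sympathoadrenal genes, 11 rose and 2 fell, 13 adjusted over the list alone. Their median was 1.79, or 1.07 at the limit (camera, adjusted p = 0.00768, and adjusted p = 0.705 with an estimated correlation). CHGA rose by 7.36 ± 0.09 (log2, SE) with 1 of the 2 Monolayer arrays under the limit, ELAVL4 at least 201-fold and INSM1, a neuroendocrine transcription factor, at least 41.4-fold. Without x_at and s_at probe sets this call was lost (adjusted p = 0.165, range 0.000491 to 0.165), and with no filter the median was 0.39. Of 23 neuronal differentiation genes, 11 rose and 3 fell, 14 adjusted over the list alone. The median was 1.17, or 0.68 at the limit (camera, adjusted p = 0.0221, and adjusted p = 0.705 with an estimated correlation). STMN2 rose at least 5.33-fold. That call was lost without iCSC replicate 2 (adjusted p = 0.0979, median 0.74) and with values under 5 set to 5 (0.0679), with a range of 0.000491 to 0.0979, and the median was 0.69 with chromosome medians removed.

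Several groups that were lower in Sphere were lower in iCSC too. Of 20 SRF, YAP and cytoskeletal targets, 14 fell and 3 rose, 17 adjusted over the list alone. Their median was -1.84 (camera, adjusted p = 0.00101, and adjusted p = 0.705 with an estimated correlation). CCN2 fell at least 45.3-fold and ANKRD1 at least 29.2-fold, and with no filter the list's median was -1.07. Of 21 endoplasmic reticulum genes, 16 fell and 3 rose, 19 adjusted over the list alone. The median was -0.74 (camera, adjusted p = 0.00293, and adjusted p = 0.705 with an estimated correlation). SDF2L1 changed by -1.65 ± 0.19 and MANF by -1.45 ± 0.19, while ERN1 rose by 1.68 ± 0.15. Of 22 TGF-beta and BMP genes, 13 fell and 5 rose, 19 adjusted over the list alone. Their median was -1.21, or -0.78 at the limit (camera, adjusted p = 0.0200, and adjusted p = 0.578 with an estimated correlation). NOG fell at least 38.5-fold and TGFBR2 changed by -3.75 ± 0.24, while the ligand BMP7 rose at least 33.8-fold. The list's call was lost without the filter on dim probe sets (adjusted p = 0.113, median -0.58) and without x_at and s_at probe sets (0.193, median -0.71), with a range of 0.00778 to 0.193.

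Of 36 G2/M and mitosis genes, 18 fell and 1 rose in iCSC against Monolayer, 19 adjusted over the list alone. The median was -0.37 (camera, adjusted p = 0.0138, and adjusted p = 0.796 with an estimated correlation). The spindle genes HMMR and CKAP2L changed by -0.95 ± 0.13 and -1.27 ± 0.21. This call was lost without iCSC replicate 1 (adjusted p = 0.0837, median -0.23) and without x_at and s_at probe sets (0.0621), with a range of 0.00219 to 0.0837. Of 34 hypoxia and glycolysis genes, 13 fell and 5 rose, 18 adjusted over the list alone. Their median was -0.21 (camera, adjusted p = 0.0426, and adjusted p = 0.705 with an estimated correlation). Members that fell included the vasodilator peptide ADM and the stress-induced NDRG1, at least 8.31-fold and 4.45-fold, and the secreted STC2, by -4.75 ± 0.17. The hypoxia call was lost without Monolayer replicate 1 (adjusted p = 0.0704), iCSC replicate 1 (0.0784) or iCSC replicate 2 (0.0523, median -0.34), without the filter (0.325), with the stricter filter (0.0589) and without x_at and s_at probe sets (0.0950), with a range of 0.0143 to 0.325, and the median was -0.37 with chromosome medians removed. Chromosome medians in this comparison were -0.59 for chromosome 14, -0.41 for chromosome 5, -0.39 for chromosome 3, 0.54 for chromosome 12 and 0.41 for chromosome 9.

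The overlap of both comparisons with Monolayer shows how far Sphere and iCSC moved alike. Genes called higher in both numbered 2099 and genes called lower in both 1985, where independent lists would share 909 and 808. In 254 genes the calls ran in opposite directions. Simulated data sets with no change shared at most 1 call in each direction. Hardly any gene is called when none changes, so that count cannot show how much overlap the shared controls create. The fold changes correlated across genes with r = 0.711 against a simulated mean of 0.499, and their covariance was 2.05 against 0.0200 simulated, a difference of 2.03. The same sign was found in 76.7% of genes and in 66.7% of simulated ones. When no gene changes, the simulated correlation and share of signs follow from the shared arrays alone. They are therefore no baseline for data in which many genes change. Splitting the Monolayer arrays would leave 1 per comparison, so the controls were not split, and part of the excess over independent lists may come from the shared controls. Of the 4084 genes that moved the same way, 1358 also differed between iCSC and Sphere. Among genes measured in some cultures and under the limit on both arrays of others, 434 were measured in Sphere and iCSC and not in Monolayer, 170 in iCSC alone, 248 in Sphere alone, 221 in Monolayer alone, 162 in Monolayer and iCSC, and 84 in Monolayer and Sphere.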

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

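The test that shuffles blocks of neighbouring genes, the removal of chromosome medians and the values with genes at the limit or measured in both cultures were chosen after the results had been seen, and the other tests before.

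Probe sets without a single gene symbol stood outside the gene tests, and many of them differed between the cultures. Of 2500 that passed the filter, 1584 without a symbol and 916 with several, 1186 were called in Sphere against Monolayer (622 higher, 564 lower), 660 in iCSC against Sphere (368 higher, 292 lower) and 1175 in iCSC against Monolayer (654 higher, 521 lower). They drew attention because they are signal in data on which the comparisons of genes do not draw.

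Fold changes between the cultures shifted by chromosome, and in iCSC against Sphere the median was -0.67 over 343 genes of chromosome 14 and 0.47 over chromosome 15. The test planned first, circular shifts along the genome, gave as extreme a median in 7.78% of 10000 shifts here, 60.7% in Sphere against Monolayer and 39.3% in iCSC against Monolayer, all above the 5% set for it, but it keeps runs as long as a chromosome whole. In the later test, 0.01% of 10000 shuffles of blocks of 20 neighbouring genes were as extreme, the smallest share possible. The other comparisons gave 0.53% and 0.06%. These shuffles break every run longer than a block and were added after the shifts were seen. They argue only against independent blocks of 20 genes, and chance is not ruled out. In iCSC against Sphere, 92.1% of 63 blocks on the 4 most shifted chromosomes moved with their chromosome. The share was 84.3% in iCSC against Monolayer and 79.7% in Sphere against Monolayer, with 80% set in advance against clusters of co-regulated neighbours. The shifts were spread along these chromosomes. As the chromosomes were chosen by the same fold changes, which favours such agreement, clusters of co-regulated neighbours stay open. Copy number differences are possible as well. The fold changes of 62 ribosomal protein and oxidative phosphorylation genes tracked their chromosome's median with a Spearman rho of 0.396 (permutation p = 9.00e-04). The permutation treated genes as independent although those of a chromosome share its median, so this p-value may be too small. In the comparisons of Sphere and iCSC with Monolayer rho was 0.409 and 0.516. Cells with different chromosome numbers may make up the cultures, through spheroid culture, 5AdC or separate stocks, which no DNA measurement tested.

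The 10 measured cancer-testis genes were higher in iCSC than in Sphere. Other scalings of the deposited values moved the list's median by at most 0.0185 (log2). GCRMA had already brought the arrays to a common distribution, so a renewed scaling could hardly move any list. It does not test the scaling within GCRMA. Cross-hybridisation between the near-identical members of a family remains open: the members outside the families had a median of 2.91, or 1.43 ± 1.60 (SD) with values under 5 at the limit, from only 2 genes, TEX14 (at least 5.89-fold) and PRAME (log2 change 0.29), and PRAME was not called without Sphere replicate 2 (0.27, limma, adjusted p = 0.0689, range 0.0127 to 0.0689) or without the variance trend (0.0623), with its change about as large. Other members outside the families, such as DAZL, DDX4 and SYCP3, did not enter the test. Without probe sets of the suffixes x_at and s_at the list was still called (camera, adjusted p = 0.00751). That alternative did not reach SSX1, MAGEA1, MAGEA6, MAGEA12 or TEX14, so it speaks only for other members. Loss of DNA methylation after 5AdC is the biological explanation the design offers, and it could not be tested without methylation data.

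Sympathoadrenal genes were lower in iCSC than in Sphere. A smaller share of one neuroblast-like cell type would lower its markers alike if no other cells expressed them. This was tested on the 9 list genes with a mean under log2 5 in Monolayer and above it in Sphere. The SD of their fold changes was 8.25 times their mean SE, or 6.32 times with values under 5 at the limit. Over the 7 genes measured in both cultures it was 5.67 times, from -5.27 for CHGB to 0.36 for ELAVL4. The values argue only against a type that alone expresses these genes, and whether other cells express them was not tested. ELAVL4, not called here (limma, adjusted p = 0.249), was called higher without iCSC replicate 2 (0.72, adjusted p = 0.0120) and with the mean of its probe sets (0.65, adjusted p = 0.0295), with a range of 0.0120 to 0.969. Chromosome shifts may account for part, since the list's median was -1.05 after chromosome medians were removed, 62.6% of the median before. The earlier 5AdC exposure is the biological explanation the design gives, and it remains open.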

How the results depend on the processing

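Of 157 pairs of a gene and a comparison named in the text, 140 kept their outcome, called or not called, under every alternative run for them, 13 lost a call and 4 gained one under some, and none changed direction, but leaving out x_at and s_at probe sets reached only 104 of the pairs. Stricter thresholds lowered the counts by their construction: with a change of at least 2-fold as well, 2994 genes were called in Sphere against Monolayer, 1730 in iCSC against Sphere, 2632 in iCSC against Monolayer and 1759 alike in both comparisons with Monolayer, and at an adjusted p under 0.01 the count of iCSC against Sphere was 2354. Without variance moderation it was 2281, and the cause was not tested. Leaving out each array in turn gave 4530 to 6604, 2574 to 3883 and 3957 to 5646 calls in the same order and 2741 to 4110 shared ones. The lists called numbered 0, 0 and 0 with an estimated correlation and 20, 17 and 19 with fry, which asks another question. Of the 9, 7 and 9 lists that camera called at the preset correlation, fry kept 8, 6 and 8. It did not call the S phase genes in Sphere against Monolayer (fry, adjusted p = 0.0907). The G2/M genes in iCSC were not called either, against Sphere (fry, adjusted p = 0.158) or Monolayer (0.0954). With chromosome medians removed, 6081, 3457 and 5552 genes, 4028 shared genes and 10, 7 and 10 lists were called. Signal near background limits genes measured in only 1 of the cultures compared, since their change is known only as a lower bound and a zero spread of dim values can lower p.

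With the replicate number as a block, 6219, 4106 and 5891 genes, 4137 shared genes and 10, 7 and 9 lists were called. The numbers do not pair the samples as far as the data show: deviations of replicate 1 from its culture's mean correlated at 0.0186 between Monolayer and Sphere, -0.0530 between Monolayer and iCSC and 0.173 between Sphere and iCSC.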

Other observations

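Some regulators of chromatin were higher in iCSC. DNMT3A and DNMT3B, which place new DNA methylation, were 1.23 ± 0.11 and 2.40 ± 0.18 (log2, SE) higher in iCSC than in Sphere and 1.77 ± 0.11 and 2.02 ± 0.18 higher than in Monolayer (limma, largest adjusted p = 0.000346). JARID2, a partner of the Polycomb complex PRC2, rose by 1.39 ± 0.14 and 2.65 ± 0.14, and the chromatin remodeller CHD7 by 0.88 ± 0.11 and 2.34 ± 0.11 (largest adjusted p = 0.00122). Against Sphere, however, 2 of 15 genes of the DNA methylation machinery were higher and 2 lower, 3 adjusted over the list alone, and 6 of 17 Polycomb and repressor genes were higher and 1 lower, 7 adjusted over the list alone (camera, adjusted p = 0.337 and 0.271). Against Monolayer, 8 of 15 genes of the DNA methylation machinery were higher and 3 lower in iCSC, 12 adjusted over the list alone, and 10 of 17 Polycomb and repressor genes were higher and 2 lower, 13 adjusted over the list alone, but camera called neither list (adjusted p = 0.504 and 0.0768). Only 8 of the 22 pluripotency and stem cell factors entered the test. Among these 8, 5 were higher and 2 lower in iCSC than in Sphere, 7 adjusted over the list alone. The higher ones include SOX2, PROM1 and MYCN, which entered the test through iCSC, so the filter set their direction. Camera did not call the list (adjusted p = 0.113). Of 9 drug efflux and aldehyde dehydrogenase genes, 3 were higher and 3 lower in Sphere than in Monolayer, and 4 were higher and 2 lower in iCSC than in Monolayer, 6 adjusted over the list alone in each, and camera called the list in neither (adjusted p = 0.711 and 0.430). Among the higher ones, ALDH2 rose at least 52.9-fold in Sphere and 84.1-fold in iCSC, and ALDH1A3 at least 44.2-fold and 34.5-fold (limma, largest adjusted p = 6.20e-06).

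Some genes reversed between Sphere and iCSC. TFAP2B, a neural crest factor, rose at least 69.7-fold from Monolayer to Sphere and changed by -5.60 ± 0.36 (log2, SE) from Sphere to iCSC, where 1 of the 2 arrays lay under the limit, and ZIC2, a neural progenitor factor, fell at least 11.7-fold and rose at least 23.3-fold (limma, largest adjusted p = 6.68e-05). The imprinted gene MEST fell from 14.52 ± 0.06 in Monolayer to 10.71 ± 0.52 in Sphere and stood at 14.71 ± 0.05 in iCSC, and the interferon-induced membrane protein IFITM1 changed by -6.17 ± 0.25, with 1 of the 2 Sphere arrays under the limit, and then by 4.03 ± 0.25 (largest adjusted p = 5.49e-05). Other genes were not chosen for a reversal. The immunoproteasome subunit PSMB8 rose at least 23.5-fold from Monolayer to Sphere and read 9.04 ± 0.01 in iCSC. Among matrix genes, the proteoglycans LUM and DCN rose in Sphere, LUM by 5.65 ± 0.15 and DCN at least 49.8-fold (adjusted p = 9.20e-07 and 9.05e-07), while 17 of 30 collagen and matrix genes fell and 10 rose, 27 adjusted over the list alone, and camera did not call the list (adjusted p = 0.405).

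Few markers of other cell types were measured in these cultures: 4 of 18 epithelial and endothelial, 3 of 16 glial and 1 of 16 haematopoietic markers passed the filter. KRT18, an epithelial keratin, read 12.77 ± 0.12 in Monolayer, 7.87 ± 0.36 in Sphere and 8.13 ± 0.19 in iCSC. On the single arrays its partner KRT8 read 10.07 and 9.88, 6.66 and 6.33, and 4.18 and 4.73 in the same order, and the endothelial receptor TEK read 7.85 and 7.70 in Monolayer and lay under the limit in Sphere and iCSC. The glial and neural crest receptor NGFR read 9.80 and 9.87 in Monolayer, 8.55 and 8.31 in Sphere, and 4.82 and 5.28 in iCSC. In the same order ERBB3 read 5.15 and 5.21, 4.32 and 4.89, and 7.74 and 7.08.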
